A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

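Poly(A)-enriched RNA from yeast that overexpressed KIN28 or POG1 was labelled and hybridized to 4 Affymetrix YG-S98 arrays, 1 per overexpressed gene and time, with 15 µg of fragmented cRNA at 45 °C for 18 h. Cells grew at 25 °C in synthetic complete medium with drop-outs and 2% glucose, and were sampled before and 60 min after 200 mM LiCl. Each sample file holds a deposited intensity per probe set on a linear scale, made by the authors with summary software not given in the sources used here. It also holds a deposited ratio, in which the authors divided the intensity by a constant per array that equals the array's median. The series-wide value table holds the same intensity to rounding. The files hold no detection calls.

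The deposited intensity was used. Each array was scaled so that the median over the probe sets above the floor on all 4 arrays was equal, with factors of 1.19 and 0.903 for the KIN28 culture at 0 and 60 min and 0.845 and 1.11 for the POG1 culture. A floor was set at the 20th percentile of each array, which gave scaled floors of 10.4, 11.0, 10.8 and 11.5 in the same order, and a probe set above it was called detected. Of the probe sets, 60 were controls, 6504 matched 1 gene in the annotation, 328 several genes and 2443 none. Genes were measured as the mean log2 signal of their 1-gene probe sets, with suffixed sets, which can detect related sequences, used for the 211 genes that had no other. This gave 5656 genes, 252 of them averaged over more than 1 probe set. Genes on shared probe sets, among them many ribosomal protein paralogs, most histones, ENA1 and ENA2, were left out. The number of arrays limits the precision, since there was 1 per group.

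The 5 comparisons were the 60 min over 0 min response of each culture, the KIN28 over the POG1 culture at 0 min and at 60 min, and the difference of the responses. No test was run. No comparison has replicates, and a model with additive gene and time effects, which would leave 1 residual degree of freedom for the shared lithium response, was not fitted. Genes detected on at least 1 array of a comparison were counted when they differed at least 2-fold; for the difference of responses, detection was needed in each culture. For 43 gene lists fixed beforehand, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list with at least 5 measured genes was called outside the random range beyond the 2.5th or 97.5th percentile. Over 39 lists tested in each response and at 60 min and 38 in the other comparisons, some medians fall outside by chance. The percentile treats genes as independent, which co-regulated genes are not.

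Genes were named by a rule fixed before the data were examined. It took KIN28, POG1 and RSP5, the 12 largest increases and 12 largest decreases in each response, 8 and 8 in each comparison of cultures, and 6 and 6 in the difference of responses, among named protein-coding genes detected on the arrays compared. It added up to 4 genes per direction detected on 1 side only, given as bounds, and from each list up to 4 members in the direction of its median plus any member at least 2-fold the other way. Outside the rule, URA4 and URA10 were picked for the closing section once URA1 and URA3 had been seen but before their own values were. The other pyrimidine genes given there, URA2 and PPR1 among them, were not part of that test. The genes with opposite responses and the RNA classes were chosen after their values were seen.

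Alternatives fixed beforehand were the deposited ratio, quantile normalization, 75th percentile scaling, lowess per comparison, no floor, a floor at the 40th percentile, no detection filter, detection on every array, the series-wide value table, suffixed probe sets left out, probe sets one by one, thresholds of 1.5-fold and 3-fold, unmatched random lists and lists without shared genes. Signals with no scaling, scaling by the bacterial hybridization controls and a floor at the 95th percentile of the negative controls were added after the data were seen. Alternatives used 2000 random lists. The steps were tested on simulated data with a noise SD of 0.2 (log2) and 200 changed genes. At least 98% of the changed genes were recovered and 2 of 5179 unchanged genes were called. Of 100 null lists 3 lay outside the random range, and 20 of 20 shifted lists lay above it. The simulated noise was lower than the spread of 1 probe set on the real arrays, 0.46 to 0.67. The changed genes were chosen well above the floor, and the null lists were drawn at random. The simulation checks the code and gives no rate of false calls for the real counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.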

Results

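The study measured messenger RNA in budding yeast (Saccharomyces cerevisiae) that overexpressed either of 2 transcription-related genes, before and 60 min after lithium chloride was added to the culture at 200 mM. Lithium is a toxic cation that imposes both ionic and osmotic stress. KIN28 (YDL108W) encodes the kinase subunit of the general transcription factor TFIIH, which phosphorylates the tail of RNA polymerase II. POG1 (YIL122W) encodes a nuclear factor linked to recovery from mating pheromone arrest. The series title places both in the setting of stress sensitivity caused by mutation of RSP5 (YER125W), which encodes an essential ubiquitin ligase. Each combination of overexpressed gene and time was represented by 1 array, 4 arrays in all, and no combination was replicated. Every difference below describes these arrays and carries no test and no p-value. The labels do not give the RSP5 genotype, nor whether both times came from the same flask; "culture" below means the arrays of 1 overexpressed gene. They name media without leucine, uracil or both, but not which culture had which, and a culture with an empty vector was not analysed here. Nor was an untreated culture at 60 min, so each change from 0 to 60 min, called a response below, combines lithium with time in culture.

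The median deposited signal over all probe sets of an array was 41.8 in the KIN28 culture at 0 min, 54.3 in the KIN28 culture at 60 min, 60.6 in the POG1 culture at 0 min and 48.0 in the POG1 culture at 60 min. After scaling, 5287, 5321, 5305 and 5239 of 5656 genes lay above the floor on these arrays in the same order. A gene is called higher or lower when its scaled signals differed at least 2-fold, and "at least N-fold" marks a gene whose dimmer array was at or below the floor. How far 2 readings of one gene can differ was taken from genes with 2 probe sets. In the KIN28 response the log2 changes of such pairs were more than 2-fold apart for 17 of 101 genes, and the spread of 1 probe set was 0.67 on the log2 scale. In the POG1 response the same spread was 0.61, with 17 of 97 genes more than 2-fold apart. For the comparisons between cultures it was 0.47 at 0 min and 0.46 at 60 min. There 9 of 102 and 10 of 101 genes were more than 2-fold apart, 8.8% and 9.9%. These values cover differences between probe sets and leave out differences between cultures. Of all genes compared between cultures, 7.9% at 0 min and 9.9% at 60 min differed at least 2-fold. The calls between cultures were thus about as frequent as such disagreement of probe sets. The 3' to 5' signal ratio, a measure of RNA integrity, was 7.50 for SRB4 in the KIN28 culture at 0 min against 4.32, 3.70 and 4.65 on the other arrays in the order above. For SPT15 it was 2.79, 3.27, 3.83 and 2.34 and for ACT1 1.92, 1.31, 1.66 and 1.73 on the 4 arrays.

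The overexpressed genes matched the labels. KIN28 gave a scaled signal of 3563 and 3181 in the KIN28 culture at 0 and 60 min, against 59.2 and 46.4 in the POG1 culture, a difference of 60.2-fold and 68.6-fold. POG1 gave 2975 and 3990 in the POG1 culture against 10.8 and 9.58 in the KIN28 culture, where the first value was just above the floor and the second below it. The difference was 274-fold at 0 min and, against the floor, at least 363-fold at 60 min. The 0 min signal lay below the 95th percentile of the array's negative controls, and against that level the difference was at least 142-fold. RSP5 differed little between the cultures, with signals of 214 and 293 in the KIN28 culture and 187 and 283 in the POG1 culture. Its signal at 60 min was 1.37-fold and 1.51-fold that at 0 min. The marker gene URA3, which encodes a pyrimidine biosynthesis enzyme used to select plasmids, was 8.84-fold lower in the KIN28 culture at 0 min and 4.97-fold lower at 60 min. LEU2, another selection marker, gave between 1580 and 3489 on the 4 arrays. Cultures with different plasmid markers or drop-out media would differ in such genes, so the comparisons between cultures cannot separate the overexpressed gene from its plasmid and medium.

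**Figure D1:**
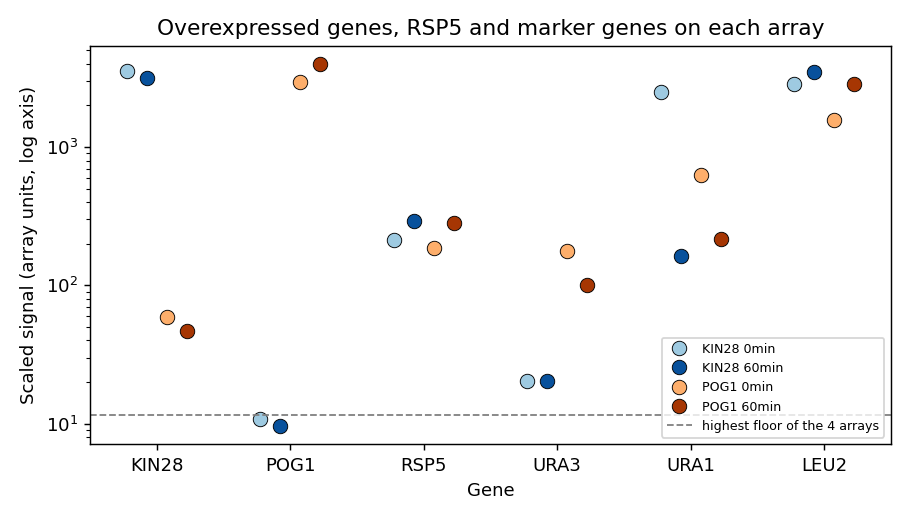
Scaled signal (array units, log axis) of the 2 overexpressed genes, RSP5 and 3 pyrimidine or leucine biosynthesis genes, 1 point per array and the highest of the 4 array floors as a dashed line. KIN28 lies at 3563 and 3181 in its own culture and at 59.2 and 46.4 in the other, POG1 at 2975 and 3990 against 10.8 and 9.58, and RSP5 between 187 and 293 on every array.

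The first comparison asks how the KIN28 culture changed over 60 min in lithium. Of 5460 genes above the floor on at least 1 of its 2 arrays, 679 were higher and 660 lower at 60 min. Genes of the general stress response were among the largest increases. HSP12, a membrane-protecting heat shock protein, was 31.9-fold higher, the cytosolic catalase gene CTT1 19.8-fold and DDR2 14.3-fold. GPP2, which encodes the last enzyme of glycerol synthesis, was 25.9-fold higher. ALD3, an aldehyde dehydrogenase gene with a close copy next to it and so uncertain, was 27.2-fold higher. The pentose phosphate genes SOL4 and NQM1 were 16.7-fold and at least 136-fold higher. HBT1 was at least 155-fold higher, FMP45 at least 72.2-fold and RTC2 at least 20.1-fold. The arginine biosynthesis gene ARG1 had the largest increase among named protein-coding genes above the floor on both arrays, 44.5-fold. PIR3, a cell wall protein gene, was 31.3-fold higher, TMT1 20.4-fold, RTC3 15.9-fold, RTN2 15.5-fold and ARO5 14.9-fold. The 0 min signals of TMT1 and RTN2 lay below the 95th percentile of the negative controls, which gives at least 17.8-fold and 14.0-fold. At that level the bounds of HBT1, NQM1, FMP45 and RTC2 are 74.2-fold, 65.0-fold, 34.6-fold and 9.62-fold.

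Among the gene lists fixed beforehand, the osmotic stress list had a median log2 change of 2.28 in the KIN28 response, with 16 of 20 measured genes higher and 0 lower. The list of targets of the stress regulators Msn2 and Msn4 had 33 of 39 genes higher, 0 lower and a median of 2.05. Trehalose and glycogen genes, which store carbohydrate, had 11 of 17 higher with a median of 1.47. PGM2 was 5.85-fold higher, TSL1 4.62-fold, TPS2 4.51-fold and GPH1 3.91-fold, and PGM1 was the member lower at 60 min, by 2.13-fold. All 3 medians lay above the middle 95% of random lists matched on expression. These lists share members such as CTT1, HSP12 and ALD3 and are not independent of one another.

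Protein synthesis genes moved the other way in the KIN28 culture. Of 96 ribosome biogenesis genes, 80 were lower and 0 higher, with a median log2 change of -1.83. NSR1, a nucleolar protein gene, was 11.3-fold lower, the RNA helicase gene DBP2 10.3-fold, NOG2 10.2-fold and ERB1 7.56-fold. The nucleolar genes HCA4, NOC4, ENP2 and SDA1 were at least 11.6-fold, 9.46-fold, 8.72-fold and 7.59-fold lower. Of 81 ribosomal protein genes measured by probe sets that match 1 gene in the annotation, 61 were lower and 0 higher, with a median of -1.31. RPS22B was 13.7-fold and RPL22B 8.72-fold lower. RPL7B and RPS9A were 21.4-fold and 10.4-fold lower, each on a probe set that can also detect related sequences. Paralogous ribosomal genes are close in sequence, so single members are uncertain. Translation factor genes had 8 of 15 lower and a median of -1.02, among them TEF4 at 3.77-fold and RPG1 at 3.7-fold. Purine biosynthesis genes had 12 of 18 lower and a median of -1.39, led by ADE17 at 12.8-fold, IMD4 at 6.74-fold, ADE1 at 6.24-fold and SHM2 at 5.2-fold. All 4 medians lay below the random range. The purine salvage gene HPT1 was 14.3-fold lower, the pyrimidine genes URA1 and URA7 15.3-fold and 10.4-fold, the ribose phosphate isomerase gene RKI1 12.8-fold, and the methionine adenosyltransferase gene SAM1, a close copy of SAM2, 15.2-fold. The glucose transporter gene HXT2 was 13.4-fold lower.

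Amino acid biosynthesis genes controlled by Gcn4 had 16 of 43 members higher and 0 lower in the KIN28 response, with a median log2 change of 0.71. Among genes above the floor on both arrays, the largest after ARG1 were LYS1 at 8.93-fold, HIS5 at 6.03-fold and TRP3 at 5.64-fold. Proteasome genes had 12 of 34 higher and a median of 0.72, with RPN9 at 2.69-fold, RPT2 and UMP1 at 2.54-fold and RPN7 at 2.39-fold. The ubiquitin list had a median of 0.45, with 8 of 36 higher and 2 lower. The polyubiquitin gene UBI4 was 4.05-fold higher, ROG3, which encodes an adaptor of Rsp5, 4.06-fold, the ubiquitin-conjugating enzyme gene UBC5 3.65-fold and ECM21 3.61-fold. UBP3 and RPS31 were 2.86-fold and 2.6-fold lower. The 0 min signal of ROG3, 13.1, lay below the 95th percentile of the negative controls, so its fold is less certain. Nitrogen catabolite genes (median 0.62), gluconeogenesis and glyoxylate genes (0.77), peroxisome and fatty acid oxidation genes (0.63), oxidative stress genes (0.45), the mitotic Clb2 cluster (0.62) and markers of a cells (1.01 over 5 genes) also lay above the random range. The thioredoxin peroxidase gene TSA2 was 9.85-fold higher, CLB2 2.42-fold and GAP1 2.7-fold. Ergosterol genes (median -0.53), lipid genes around OLE1 (-0.62) and G1 cyclin and start genes (-0.47) lay below it. ERG3 was 4.29-fold lower, INO2 3.38-fold and CLN2 2.59-fold, while OLE1 itself was 2.44-fold higher.

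All 4 markers of alpha cells were lower in the KIN28 response, and MF(ALPHA)2, a mating pheromone gene, had the largest decrease among named genes above the floor on both arrays, 24.6-fold. SAG1 was 4.21-fold lower, the pheromone receptor gene STE3 3.98-fold and MF(ALPHA)1 2.81-fold. Lists expected to hold ion homeostasis genes stayed within the random range. Cation transport genes had a median log2 change of -0.04, with NHX1 2.02-fold higher and PMA2, TRK1 and SAT4 2.41-fold, 2.15-fold and 2.07-fold lower. Targets of the calcium-responsive factor Crz1 had a median of 0.26, with YPS1 2.11-fold higher and CMK2 3.51-fold lower. The lithium-exporting ATPase genes ENA1 and ENA2 share their probe sets with related genes in the annotation and were not measured alone. Heat shock genes had a median of -0.29, which lay at the 18.1th percentile of random lists, although SSA4 was 4.49-fold and SSE2 3.59-fold higher. The KIN28 response rests on 1 array per time. Under alternatives added after the data were seen, 1241 genes were higher and 374 lower without scaling, and 1404 higher and 342 lower when scaled by hybridization controls, which moved the median of all genes from 0.01 to 0.40 and 0.48.

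The second comparison asks the same of the POG1 culture. Of 5456 genes, 689 were higher and 751 lower at 60 min. The largest increases again included many stress genes. Among genes above the floor on both arrays, NQM1 was 138-fold higher, HBT1 68.7-fold, ALD3 56.7-fold, GPP2 30.1-fold, HSP12 28.5-fold, the transketolase gene TKL2, with 1 of its probe sets at the floor, at least 24.0-fold, RTC3 20.8-fold, CTT1 16.5-fold, MSC1 16.0-fold and PIR3 14.1-fold. The 0 min signals of NQM1, HBT1 and TKL2 lay below the 95th percentile of the negative controls, which gives at least 101-fold, 61.0-fold and 10.6-fold and leaves their order open. ARG1 was 17.4-fold higher. SSA4, a heat-inducible Hsp70 gene, was 17.3-fold higher. FMP45, FMP48, GRE1 and ARG3 were at least 75.1-fold, 29.9-fold, 14.8-fold and 8.29-fold higher, or 30.7-fold, 12.2-fold, 6.06-fold and 3.39-fold at the level of the negative controls. The osmotic stress list had 19 of 20 genes higher with a median log2 change of 2.30, the Msn2 and Msn4 list 34 of 39 with a median of 2.48, and the trehalose and glycogen list 13 of 17 with a median of 1.72. TPS2 was 10.3-fold higher, PGM2 10.1-fold, TSL1 5.88-fold and GSY2 5.57-fold, and PGM1 was again lower, by 2.33-fold.

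Ribosome biogenesis genes were lower in 66 of 96 cases in the POG1 response and higher in 0, with a median log2 change of -1.43. RLP7 was 9.71-fold lower, BUD21 8.9-fold, NSR1 6.82-fold and the RNA polymerase I gene RPA135 5.7-fold. NOP19 and FYV7, which also act in ribosome assembly, were at least 9.87-fold and 8.35-fold lower, and the RNA polymerase III gene RPC34 was 10.6-fold lower. Ribosomal protein genes were lower in 52 of 81 cases with a median of -1.21, among them RPL22B at 13.8-fold, RPS26B at 12.4-fold and RPL7B at 11.2-fold, the last on a probe set shared with related sequences. Translation factor genes had 8 of 15 lower and a median of -1.02, with the cap-binding protein gene CDC33 5.73-fold lower. Purine genes had 8 of 18 lower and a median of -0.92, with ADE17 at 7.03-fold and ADE6 at 3.93-fold. SAM1 was 13.5-fold lower, HPT1 11.0-fold, the adenine deaminase gene AAH1 at least 10.7-fold, the cytochrome c gene CYC1 9.14-fold, DSE4 8.42-fold and PAN6 at least 9.85-fold. The 60 min signals of RPC34, RLP7, BUD21, DSE4 and 1 of the probe sets of RPL7B lay below the 95th percentile of the negative controls. Against that level they were at least 4.84-fold, 8.57-fold, 5.56-fold, 6.77-fold and 8.32-fold lower, and NOP19, FYV7, AAH1 and PAN6 at least 4.4-fold, 3.72-fold, 4.75-fold and 4.39-fold, which leaves their order open.

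The Gcn4 list had 19 of 43 genes higher and 1 lower (LYS4, 2.39-fold) in the POG1 response, with a median log2 change of 0.87, and LYS1 was 9.85-fold, TRP3 6.08-fold and HIS5 5.45-fold higher. Ubiquitin genes had a median of 0.62 with 7 of 36 higher and 0 lower, among them HUL4 at 6.54-fold and UBI4 at 6.46-fold. Proteasome genes had 7 of 34 higher and a median of 0.63, with RPT2 at 2.38-fold. Nitrogen catabolite genes (median 0.65), gluconeogenesis genes (0.69), drug resistance genes (0.58), oxidative stress genes (0.45), glycolysis genes (0.39) and heat shock genes (0.36) lay above the random range, and the heat shock median became -0.03 both without scaling and when scaled by hybridization controls, which lowered all genes and left it above their median. HSP78 was 3.31-fold higher, SSE2 3.42-fold and HSP42 2.13-fold. Phosphate genes had a median of -0.89, with 6 of 15 lower and 3 higher. The phosphate transporter gene PHO84 was 3.96-fold lower and VTC3 2.94-fold, whereas PHM7 was 5.29-fold, PHM8 3.21-fold and PHO8 2.32-fold higher. Ergosterol genes had 6 of 25 lower and a median of -0.67, led by ERG3 at 5.51-fold and ERG4 at 3.94-fold. The alpha-cell markers were lower in 4 of 4 cases, with MF(ALPHA)2 at 15.5-fold, MF(ALPHA)1 at 9.9-fold, STE3 at 4.07-fold and SAG1 at 3.23-fold. Cation transport genes had a median of 0.13, with the calcium pump gene PMC1 2.38-fold higher and ENA5 3.5-fold lower, and Crz1 targets a median of -0.12. Both medians lay within the random range. The 60 min signal of ENA5, 16.7, lay below the 95th percentile of the negative controls, so its fold is less certain. ENA1 and ENA2, not measured alone, are not among the genes behind the cation transport median. With 1 array per time the POG1 response has no replicate check. Without scaling 379 genes were higher and 1372 lower, and when scaled by hybridization controls 380 higher and 1363 lower, with the median of all genes moved from -0.02 to -0.41 and -0.40.

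Beyond these, several lists stayed within the random range in both responses. Their median log2 changes in the KIN28 and POG1 responses were 0.14 and 0.02 for the other TFIIH subunits, 0.16 and 0.54 for galactose genes, -0.05 and -0.07 for sulfur and methionine genes, 0.18 and -0.13 for iron genes, -0.11 and -0.01 for zinc genes, 0.17 and -0.05 for cell wall genes, and 0.13 and 0.01 for unfolded protein response genes. They were -0.30 and -0.01 for pheromone and mating genes, 0.15 and -0.16 for sporulation genes, -0.39 and 0.23 for early G1 genes, 0.03 and -0.28 for respiration genes, 0.23 and 0.01 for hexose transporters, 0.45 and 0.22 for thiamine, pyridoxine and nicotinamide genes, and 0.63 and 0.66 for other auxotrophic markers. In the thiamine and pyridoxine list SNZ1 was 14.0-fold and 9.52-fold higher in the KIN28 and POG1 responses and BNA1 8.61-fold and 5.64-fold. Histone genes were measured alone in 4 cases, too few for a percentile, and HTB2 was 3.03-fold lower in the KIN28 and 5.9-fold lower in the POG1 response. Lists called in a single response had these medians in the other. In the POG1 response a-cell markers lay at -0.01, the Clb2 cluster at 0.32 and peroxisome genes at 0.46. OLE1 lipid genes lay at -0.52 and G1 cyclin genes at -0.34. In the KIN28 response drug resistance genes lay at 0.50, glycolysis at -0.10 and phosphate genes at -0.15. Of such lists, only phosphate and heat shock genes left the random range in the difference of responses. The a-cell markers were too few there.

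**Figure D2:**
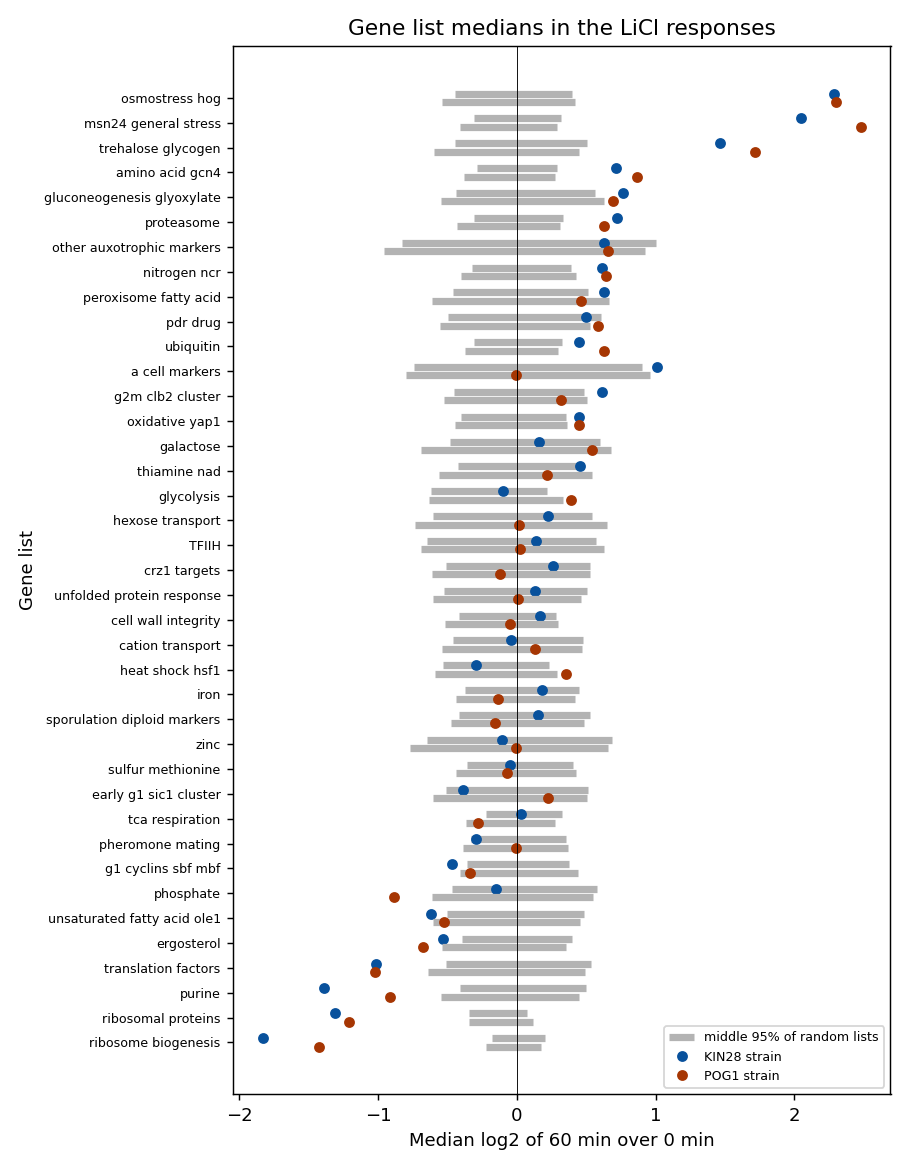
Median log2 change (60 min over 0 min) of each fixed gene list with at least 5 measured genes, as a blue point for the KIN28 culture and an orange point for the POG1 culture, with grey bars for the middle 95% of 10000 random lists matched on expression. The osmotic stress list lies at 2.28 and 2.30, ribosome biogenesis at -1.83 and -1.43, and cation transport at -0.04 and 0.13, inside its bars.

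The responses of the 2 cultures, which share no array, were set against each other over 5379 genes above the floor in each culture. Across genes, which are not independent replicates, Pearson's r was 0.74 and Spearman's rho 0.67, and 73.4% of genes changed with the same sign. Of 673 genes higher in the KIN28 culture and 681 higher in the POG1 culture, 391 were shared, against 85.2 for independent lists of those sizes. Of 655 and 747 genes lower, 399 were shared against 91.0. Opposite changes of at least 2-fold were seen for 10 genes. BSC6, IZH4, MEP1, SDS3, SMP3 and UBP16 were higher in the KIN28 and lower in the POG1 response, and SKG6, SLX8, TRF5 and VRL1 the reverse. These 10 are named because they are few. With the floor at the 40th percentile the KIN28 response of MEP1 became -0.0059 and the SDS3 difference -0.0705. Neither kept its opposite change there. The correlation was 0.81 with the floor at the 40th percentile and 0.62 with no floor.

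**Figure D3:**
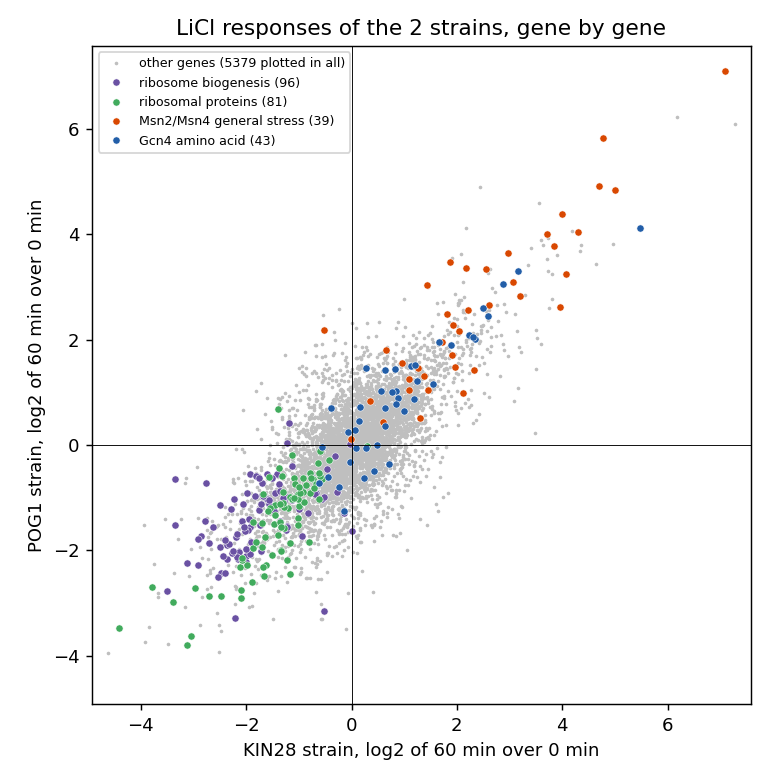
Log2 change from 0 to 60 min of each of 5379 genes in the KIN28 culture (x axis) and the POG1 culture (y axis), 1 grey point per gene and coloured points for 4 gene lists. The points follow a rising band with r of 0.74 across genes, stress genes at the upper right with medians of 2.05 and 2.48, and ribosome biogenesis genes at the lower left with medians of -1.83 and -1.43.

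The third comparison sets the cultures against each other before lithium, where the KIN28 array had the highest SRB4 ratio. Of 5439 genes, 165 were higher and 263 lower in the KIN28 culture than in the POG1 culture. Apart from KIN28, the vacuolar aminopeptidase gene APE1 was 6.49-fold higher, SSA4 4.26-fold, the phosphatidylserine decarboxylase gene PSD1 4.1-fold, the pyrimidine gene URA1 4.01-fold, OAF3 3.93-fold, RNA14 3.91-fold and PUS5 3.88-fold. Apart from POG1 and URA3, the cell wall stress reporter gene PRM5 was 7.03-fold lower, FYV4 5.63-fold, the iron-related cell wall gene FIT2 5.52-fold, HEF3 5.09-fold, ARR2 4.58-fold and the vacuolar transporter gene VMR1 4.33-fold. MOT3, PRP45, HLR1 and JID1 were at least 3.66-fold, 3.13-fold, 2.96-fold and 2.93-fold higher, and JJJ2, ARG81, SLD3 and MIH1 at least 4.47-fold, 4.03-fold, 4.02-fold and 4.01-fold lower. A higher floor, from the 40th percentile or the negative controls, took 12 of these 24 genes below 2-fold: OAF3, PUS5, FYV4, HEF3 and the 8 given as bounds. RNA14 and URA3 also had a dimmer signal below the 95th percentile of the negative controls, which gives at least 3.77-fold and 8.49-fold; for FYV4, HEF3 and OAF3 that level gives 3.1-fold, 2.73-fold and 2.01-fold, and for PUS5 1.67-fold.

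Phosphate genes were lower in the KIN28 culture at 0 min in 7 of 15 cases and higher in 0, with a median log2 difference of -0.80. PHO89 was 2.96-fold lower, SPL2 2.72-fold, PHO81 2.4-fold and PHO84 2.29-fold. The PHO89 signal of the KIN28 culture, 13.4, lay below the 95th percentile of the negative controls, and against that level PHO89 falls short of 2-fold. Cell wall genes had 6 of 31 lower and a median of -0.37, with CRH1 2.55-fold and the glucan synthase gene GSC2 2.47-fold lower besides PRM5. Iron genes had 3 of 23 lower and a median of -0.38, and respiration genes 1 of 45 lower (COX13, 2.32-fold) and a median of -0.18. Heat shock genes had a median of 0.37, with SSA4 and HSP78 (2.38-fold) higher, early G1 genes 0.38, with ASH1 3.39-fold and DSE4 2.48-fold higher and RME1 2.98-fold lower, and oxidative stress genes 0.26; without scaling these 3 medians became -0.12, -0.11 and -0.23, still above the median of all genes. Other auxotrophic markers had a median of 0.50 with 0 of 5 at 2-fold. These 8 medians lay outside the random range. The osmotic stress list (-0.08), the Msn2 and Msn4 list (-0.07), ribosomal proteins (-0.07) and ribosome biogenesis (-0.00) lay within it. Without any scaling 38 genes were higher and 931 lower, with the median of all genes at -0.46 instead of 0.02. The count of 428 genes was 250 with the floor taken from negative controls and 183 with the floor at the 40th percentile.

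After 60 min in lithium, 276 of 5439 genes were higher and 265 lower in the KIN28 culture than in the POG1 culture. Apart from KIN28, DSE4, a daughter-cell glucanase gene, was 5.4-fold higher, the RNA polymerase II tail phosphatase gene FCP1 5.03-fold, BUD21 4.99-fold, RSM19 4.93-fold, SPS100 4.57-fold, TPT1 4.42-fold and UFE1 4.4-fold. IZH4, AVT5, MRX11 and ELG1 were at least 7.67-fold, 6.42-fold, 5.92-fold and 5.18-fold higher. The helicase gene DBP2 was 6.87-fold lower, SLX8, part of a SUMO-targeted ubiquitin ligase, 4.92-fold, the G1 repressor gene WHI5 4.88-fold, PEX17 4.77-fold, MIL1 4.28-fold, PMS1 4.25-fold and MF(ALPHA)2 4.08-fold. SDA1, TYW3 and BIO5 were at least 5.86-fold, 5.52-fold and 5.18-fold lower. With the floor at the 40th percentile FCP1, MIL1, AVT5, MRX11, ELG1, TYW3 and BIO5 fell short of 2-fold. The dimmer signals of DSE4, FCP1, BUD21, SPS100 and UFE1 lay below the 95th percentile of the negative controls, which gives at least 4.19-fold, 2.18-fold, 3.0-fold, 3.28-fold and 3.71-fold and leaves their order open. At that level IZH4, AVT5, MRX11 and ELG1 are at least 3.3-fold, 2.76-fold, 2.54-fold and 2.23-fold higher. The split between higher and lower genes depended on the processing, with 247 and 304 after 75th percentile scaling, 108 and 162 with the floor at the 40th percentile, 157 and 354 with the floor from negative controls, 384 and 208 from the deposited ratio, 360 and 213 after quantile normalization, 588 and 125 without scaling and 2432 and 33 when scaled by hybridization controls. The last 4 moved the median of all genes from 0.04 to 0.15, 0.09, 0.33 and 0.94, so directions here are relative to that median.

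At 60 min the medians of ribosome biogenesis (-0.32, 13 of 95 lower and 2 higher), cell wall (-0.45, 4 of 31 lower and 2 higher), glycolysis (-0.51, 1 of 20 lower), osmotic stress (-0.45, 2 of 20 lower and 1 higher), Msn2 and Msn4 (-0.28, 2 of 39 lower and 1 higher), Crz1 target (-0.49, 2 of 14 lower and 1 higher), galactose (-0.44), iron (-0.25), purine (-0.17) and early G1 genes (-0.28) lay below the random range, and all 10 turned positive when scaled by hybridization controls, as did the Msn2 and Msn4, iron, purine and early G1 medians without scaling, and all stayed below the median of all genes, which those scalings also raised. NOC3 was 3.42-fold lower in the KIN28 culture, the osmotic stress glycerol importer gene STL1 3.16-fold, GSC2 2.66-fold and CMK1 2.4-fold, while BUD21 and UTP9 (2.76-fold) were higher within their list. Sulfur and methionine genes had 7 of 25 higher, 2 lower and a median of 0.32, with MET6 3.17-fold and MET17 and MET22 2.79-fold higher. Thiamine genes (0.38), gluconeogenesis genes (0.46) and other auxotrophic markers (0.62) also lay above the random range.

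The last comparison asks where the lithium responses of the cultures differed. Of 5379 genes, 404 had a response at least 2-fold more positive in the KIN28 culture and 393 at least 2-fold more negative. GPG1, a G protein subunit gene, had a response 9.56-fold higher in the KIN28 culture, with signals of 18.7 and 208 there against 60.2 and 70.2 in the POG1 culture. The response of CSI2 was 6.72-fold higher, of AIM3 6.64-fold, of SDS3 6.59-fold, of BUD21 6.19-fold and of TIR3 5.96-fold. The response of OAF3 was 8.06-fold lower in the KIN28 culture, VRL1 7.86-fold, SLX8 7.44-fold, TMA16 6.57-fold, DBP2 6.55-fold and the regulator gene MGA1 6.52-fold. Most of these signals were below 100, and for 9 of the 12 genes at least 1 signal lay below the 95th percentile of the negative controls, all but TIR3, SLX8 and DBP2. With the floor at that level the difference was 3.16-fold for CSI2, 1.98-fold for AIM3, 2.08-fold for SDS3, 3.76-fold for BUD21, 4.19-fold for OAF3 and 3.81-fold for MGA1, so the order of the group is open. With the floor at the 40th percentile SDS3 changed sign.

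In the difference of responses, heat shock genes had a median of -0.61, with SSA4 3.85-fold, HCH1 2.39-fold and HSP78 2.29-fold lower. SSA4 and HSP78 were already higher, and PHO84 lower, in the KIN28 culture at 0 min, and this comparison uses the same arrays as those between cultures, so it is not independent of them. Ribosome biogenesis genes had a median of -0.40, with 17 of 96 lower and 4 higher, purine genes -0.52, osmotic stress genes -0.36, trehalose and glycogen genes -0.37 and early G1 genes -0.36. All 6 of these medians turned positive without scaling and when scaled by hybridization controls, and stayed below the median of all genes, which those scalings also raised. NOC3 was 4.09-fold, NOG2 3.56-fold and ADE4 2.92-fold lower. Respiration genes had a median of 0.37 with 2 of 45 higher, the citrate synthase gene CIT1 at 2.26-fold and IDH1 at 2.16-fold. Phosphate genes had 5 of 15 higher and a median of 0.49, with PHO84 at 3.58-fold, against medians of -0.80 between the cultures at 0 min and 0.19 at 60 min, and thiamine genes a median of 0.54. Without scaling 2053 genes were higher and 84 lower, and when scaled by hybridization controls 2291 and 72, with the median of all genes moved from 0.04 to 0.83 and 0.90. Differences of 2-fold were seen for 28.9% of the 1345 dimmest genes and 5.35% of the 1345 brightest, and the count of 797 genes was 407 with the floor at the 40th percentile.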

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

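The tests of ribosomal RNA were chosen only after the result was seen; the test of dim probe sets was set out before its result.

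The transcriptional co-repressor gene SDS3 and the ubiquitin ligase gene SLX8 changed in opposite directions in the 2 cultures, as did VRL1, and all 3 were above the floor on every array. The log2 difference of responses, KIN28 minus POG1, was 2.72 for SDS3, -2.89 for SLX8 and -2.98 for VRL1. The differences were not tested. With the floor at the 40th percentile the SDS3 difference reversed to -0.0705. Signals were low, with 2 arrays of SDS3 and 1 of VRL1 below the 95th percentile of the negative controls, from 10.7 to 35.7 for SDS3, 12.9 to 63.2 for SLX8 and 19.2 to 78.2 for VRL1. The share of genes with a 2-fold difference of responses was 5.4 times higher in the 1345 dimmest genes than in the 1345 brightest (28.9% against 5.35%), so measurement error of dim probe sets may account for many such differences. A biological difference stays open and untested.

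Probe sets outside the gene comparisons carried signal. The number above the 95th percentile of the negative controls on every array was 50 of 50 for full-length Ty1 retrotransposons, 66 of 97 for transfer RNAs, 29 of 74 for small nuclear and nucleolar RNAs and 3 of 10 for ribosomal RNA controls. The 2 bright 25S ribosomal RNA control sets gave 4556 and 2673 at 0 min and 43.2 and 1518 at 60 min in the KIN28 culture, and 3743 and 1424, then 34.1 and 352, in the POG1 culture. The 2 brightest 18S sets gave 1146 and 1235, then 84.1 and 113, in the KIN28 culture and 217 and 161, then 26.2 and 53.8, in the POG1 culture, so they also differed between the cultures at 0 min.

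For the lower ribosomal RNA signals, less carry-over of intact 25S RNA into the purified messenger RNA would lower its probe sets alike. The bright 25S sets lay 5.90 log2 units apart in the KIN28 culture and 4.76 in the POG1 culture, which argues against it as the whole cause. Less carry-over of all RNA without a poly(A) tail would lower transfer RNAs too. Their median log2 changes were 0.80 (95% interval 0.48 to 1.36) and 1.03 (0.60 to 1.54), positive under every scaling, which argues against it as the whole cause. The intervals here and below come from resampling probe sets of 1 array per time. They leave out differences between arrays and between cultures. Small nuclear and nucleolar RNAs had median log2 changes of -0.74 (95% interval -1.30 to -0.61) and -0.80 (-1.18 to -0.51). In the KIN28 culture the median was -0.35 without scaling and -0.27 when scaled by hybridization controls. In the POG1 culture it was -1.19 under both. Those scalings also shift all genes. What lowered the ribosomal and small RNA signals stays open, and no biological explanation was tested.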

How the results depend on the processing

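Values without scaling, scaled by hybridization controls or with the floor from negative controls were chosen only after the data were seen; the other alternatives were planned. The labels carry no replicate numbers that pair arrays, and a model of the shared lithium response with the overexpressed gene as a block, which would leave 1 residual degree of freedom, was not fitted. Values that moved or reversed are given below, and the cause was not tested except where a threshold or floor by construction changes how many genes pass.

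All 32 largest-change genes of each response stayed at least 2-fold wherever an alternative gave a value. Chosen as the largest changes, from 7.59-fold up, they could hardly fall below 2-fold, so this says little about stability. Of 80 recomputed gene counts 62 stayed within 1.5 times, of 3005 list medians 2691 moved little, 283 moved and 31 reversed, and of 13119 values of named genes 12422 moved little, 683 moved and 14 reversed. All 75 counts of lists outside the random range stayed within 1.5 times. No scaling, hybridization controls, 75th percentile scaling and the deposited ratio shift a list and its random lists alike. The series-wide value table holds the same intensities. Counts under these alternatives could hardly change and do not show how stable the lists are. Detection settings also leave the log2 value of a gene as it was. All 1028 values of named genes stayed the same with no detection filter, the series-wide value table, the deposited ratio and 75th percentile scaling. The tallies of list medians and named genes thus include settings that could hardly move a value, and do not measure stability. Of lists called in the KIN28 response, 0 of 19 changed sign; in the POG1 response 1 of 18 did. No scaling and hybridization controls shift all genes of a comparison alike, so the sign changes of lists under them, given below, follow from that shift by construction.

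At 1.5-fold the counts were 2528 and 2767 genes in the KIN28 and POG1 responses, 1414 and 1537 between cultures at 0 and 60 min and 1930 for the difference of responses; at 3-fold they were 554, 600, 63, 129 and 242. With the floor at the 40th percentile they were 183 at 0 min, 270 at 60 min and 407 for the difference. The floor from negative controls gave 250 at 0 min. Without scaling they were 969 at 0 min and 2137 for the difference, and with hybridization controls 2465 at 60 min and 2363 for the difference. The correlation of the responses was 0.618 with no floor, 0.810 with the floor at the 40th percentile, 0.754 for genes detected on every array, 0.697 for probe sets one by one and 0.775 with the floor from negative controls.

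With the floor at the 40th percentile, genes that reversed were MEP1 (-0.0059), CTA1 (-0.007) and DUR3 (-0.0287) in the KIN28 response, OYE3 (0.0674) in the POG1 response, MEP1 (-0.11) at 60 min, and SDS3 (-0.0705), GND2 (-0.40) and YAT1 (-0.57) in the difference. With the floor from negative controls they were PRM6 (-0.16) and MLS1 (-0.0178) at 0 min, FRE4 (-0.15) and ASG7 (-0.13) at 60 min, and YAT1 (-0.18) and DCI1 (-0.24) in the difference.

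Without scaling, list medians that reversed were heat shock in the POG1 response (-0.0336); heat shock (-0.12), early G1 (-0.11) and oxidative stress (-0.23) at 0 min; Msn2 and Msn4 (0.0147), purine (0.12), iron (0.0408) and early G1 (0.0136) at 60 min; and osmotic stress (0.42), trehalose (0.41), heat shock (0.17), ribosome biogenesis (0.38), purine (0.26) and early G1 (0.43) in the difference. With hybridization controls they were heat shock in the POG1 response (-0.0281), then at 60 min Crz1 targets (0.41), osmotic stress (0.45), Msn2 and Msn4 (0.62), ribosome biogenesis (0.58), galactose (0.46), purine (0.73), iron (0.65), cell wall (0.45), early G1 (0.62) and glycolysis (0.39), and in the difference osmotic stress (0.49), trehalose (0.48), heat shock (0.24), ribosome biogenesis (0.45), purine (0.33) and early G1 (0.50).

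Values of named genes, counted per gene and comparison, were missing in 108 cases with the floor at the 40th percentile and 72 with detection on every array. They were missing in 42 with the floor from negative controls and 23 without suffixed probe sets. Signal over background limits the dim genes, since the negative controls' 95th percentile, before scaling, was 17.9, 12.3, 30.8 and 23.7 on the 4 arrays.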

Other observations

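The test of URA4 and URA10 was set out before their values were seen, and that of URA3 was chosen only after the result was seen.

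Full-length Ty1 elements, whose copies share probe sets, had median log2 responses of 0.87 in the KIN28 and 0.67 in the POG1 culture, and lay lower in the KIN28 culture by medians of -0.67 at 0 min and -0.66 at 60 min. Transfer RNA probe sets had median responses of 0.80 and 1.03. The responses kept their sign under each of the 6 other scalings, and the Ty1 median at 60 min turned to 0.24 when scaled by hybridization controls, which raised the median of all genes to 0.94.

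A hypothesis was that the higher URA1 of the KIN28 culture at 0 min reflects the pathway regulator Ppr1, whose targets include URA1, URA3, URA4 and URA10. At 0 min URA4 and URA10 were higher in that culture by 1.16 and 0.77 on the log2 scale, against 2.01 for URA1. The URA10 signal of the POG1 culture, 20.4, lay below the 95th percentile of the negative controls. Against that level the URA10 difference is smaller. URA2 differed by 0.92 and PPR1 itself by 0.12. Of the other pyrimidine genes, URA6 differed by 0.73, URA8 by 0.72, URA5 by 0.23 and URA7 by 0.13. A difference like that of URA10 was thus also seen outside the targets named. URA3 differed by -3.14, opposite to URA1, which argues against Ppr1 as the cause of the lower URA3. At 60 min the differences were -0.41 for URA1, -0.38 for URA4, 0.20 for URA10 and -2.31 for URA3, so the higher URA1 and URA4 were seen at 0 min alone. Since URA4 passed 2-fold and URA10 did not, the test left Ppr1 open for URA1 at 0 min, and plasmid and medium cannot be told apart from it in this design.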
